A study of Homo sapiens with 24 samples.

How the data were processed

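RNA from 24 human cell cultures was hybridised to Illumina expression arrays. PNT1a, an immortalised line of prostate epithelium, carried a stable HIP1 construct or an empty vector and was kept under 0.8 mg/ml of the selection drug G418. LNCaP, a prostate cancer line, was transfected transiently with HIP1 or empty vector and harvested 4 days later. The labels name 6 biological replicates in each of the 4 groups, total RNA from a column kit, a Bioanalyser check of its quality, and biotin-labelled cRNA.

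The deposited value table holds log2 probe intensities for 48803 probes on the 24 arrays, with 0 missing values. Its 24 sorted columns differ by at most 0.052 (log2), so the deposited log2 values already share a single distribution over both lines. The software and the normalization are not given in the sources used here. A second table, per the file headers, holds raw intensity per bead type for 49895 entries whose numeric identifiers are not paired with probe names. Of its 24 value columns, 6 carry names that match the labels (LNCaP with HIP1) and 18 do not and were not used, and its detection p columns hold 0 filled cells. The raw intensity columns served to learn the scale of the deposited table: percentiles of raw log2 values lay below the deposited ones by 0.009 to 0.114.

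Background correction against negative controls with a filter on detection p had been chosen for the main fit, and neither could be run on these tables. The deposited log2 values were therefore used as they stand, and dim probes were left out by signal. The background level was the mode of all log2 values (6.48) plus 3 SDs of the values under the mode (0.163 each), which gives 6.97. A probe was tested in a line when it lay above that level on at least 6 of the 12 arrays of the line, whatever their group. This kept 12238 probes in PNT1a and 12022 in LNCaP, with 10314 in both and 13946 in either. Each array had 12114 to 12122 probes above the level and a median of 6.56, and the range of the table was 5.73 to 15.52. The number of arrays limits the precision of each mean. Where the mean of a single group of a comparison lay below the level, it was replaced by the level and the value is given as a bound (at least), and fitted values are named as such where a line has no group above the level.

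Gene symbols came from the probe annotation: 28098 probes have a single symbol, 13 have several and 20692 have none. The gene IDs of 28059 probes matched the RefSeq gene table, which changed 0 symbols. Probes without a single symbol were counted but not named. The text gives genes by symbol, and the probe for HIP1 and STAT3.

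Group means were fitted with limma (version 3.58.1 in R 4.3.3) over all 24 arrays with a shared spread, with no covariate. Contrasts were HIP1-labelled minus vector arrays in PNT1a and in LNCaP, and the LNCaP effect minus the PNT1a effect. Moderated p-values were adjusted by Benjamini-Hochberg within each contrast, with calls at 0.05. Every adjusted p without another name comes from limma and is two-sided. The HIP1 probe was also tested by an exact permutation of the 12 arrays of a line. The overlap of calls was tested by a one-sided Fisher's exact test, and the effects of the lines were correlated across probes, which are not independent replicates.

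The 20 gene lists (495 genes) were fixed before the data were examined, as were the design, the contrasts and the rule for naming genes. Of the listed genes, 31 had no named probe and were not analysed here. Each gene entered a list by its brightest probe, and lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, with fry, and by exact permutation of the mean of the list per array. Adjustment ran over the lists of a contrast. The genes named are HIP1, STAT3, GDF15, the 8 largest rises and 8 largest falls per line among called genes whose 6 HIP1-labelled arrays all lay on one side of the 6 vector arrays (a gene with several probes is ranked by its most significant one), up to 4 called members of a list described (or 2 uncalled ones, as values), up to 6 genes shared in each direction pair, the 6 largest differences between lines not yet named, and markers of line identity, some of which are not reported here.

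The fit was tested on simulated data with 200 changed probes. With equal spread in both lines, changes of 0.5, 1 and 2 (log2) were recovered in 81.0%, 94.8% and 100% of PNT1a probes (12238 run), with 16 false among 198 calls. The LNCaP figures were 83.6%, 95.6% and 100% (12022 run), with 20 false among 208. With the real spread of each line, which is wider in PNT1a (median within-group SD 0.185 and 0.207) than in LNCaP (0.126 and 0.12), the shared spread gave 158 false among 344 PNT1a calls and 10 false among 193 LNCaP calls. Fitting each line alone brought these to 20 of 191 and 7 of 206, with changes of 0.5 recovered in 70.3% of PNT1a and 98.5% of LNCaP probes. The fit over both lines had been chosen before the data were examined and was kept, and counts from each line alone are given for the totals and for most lists. In the list test, a list of 25 genes shifted by 0.5 passed and 0 of 20 unchanged lists passed. The simulated probes varied independently, so this does not show how camera behaves where the genes of a list are correlated. The estimated correlation of the real integrated stress list in PNT1a was 0.355.

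Within groups the closest arrays correlated at up to 0.996 and shared at most 36 identical values, so no array was counted as a repeat of another. Identical values cannot show whether arrays shared a culture or batch. By their residuals (array minus group mean) the PNT1a arrays were cut into 3 clusters. The first held vector 1 and 2 with HIP1-labelled 3 and 4. The second held vector 3 to 5 with HIP1-labelled 1, 2 and 5. The third held both arrays numbered 6. All tests take the arrays of a group as independent, which these clusters leave open. Alternatives covered the filter, the restriction of the difference to probes tested in both lines, fitting each line alone, the replicate number as a block, array weights, a 2-fold minimum, normexp on the linear scale, cyclic loess, the list tests, arrays left out singly and in sets, and blocks from clusters of residuals. Figures were drawn with matplotlib 3.10.9.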

Results

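Gene expression was profiled on 24 arrays from 2 prostate lines, each with a HIP1 construct or an empty vector, with 6 arrays per group. PNT1a is an immortalised prostate epithelial line that, per the labels, carried its construct stably, and LNCaP is a prostate cancer line taken 4 days after transient transfection. The series title links HIP1, an endocytic adaptor protein that binds clathrin, to prostate cancer through STAT3 signalling. Values are deposited log2 intensities, with a background level of 6.97, and every array had a median of 6.56.

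HIP1 itself was measured by a single named probe (ILMN_1701403), and its signal was close in HIP1-labelled and vector arrays. The HIP1 level in PNT1a was 7.69 ± 0.21 with vector and 7.79 ± 0.35 in HIP1-labelled arrays (mean ± SD of 6). The difference was 0.10, with a 95% interval of -0.15 to 0.34 (exact permutation p = 0.543 over 924 splits, limma adjusted p = 0.562). Its upper end is a 1.27-fold rise of the probe signal, background included, over all 6 arrays of each group. In LNCaP the HIP1 signal was 7.40 ± 0.16 and 7.29 ± 0.15, a difference of -0.11 with an interval of -0.36 to 0.13 (exact permutation p = 0.232, limma adjusted p = 0.781). HIP1 signal lay above background on all 24 arrays. PNT1a HIP1-labelled array 6 had the lowest HIP1 value of its line (7.10). Without that array the PNT1a difference was 0.24 (limma adjusted p = 0.0312), and over all arrays left out and other settings the adjusted p ran from 0.0312 to 0.908. The fit that gave 0.24 kept vector array 6, which had the lowest HIP1 value of the vector group (7.30). Where the probe lies relative to the cloned part of HIP1 is not given in the sources used here, so the signal does not settle the labels, and the groups are called HIP1-labelled and vector arrays throughout.

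**Figure D1:**
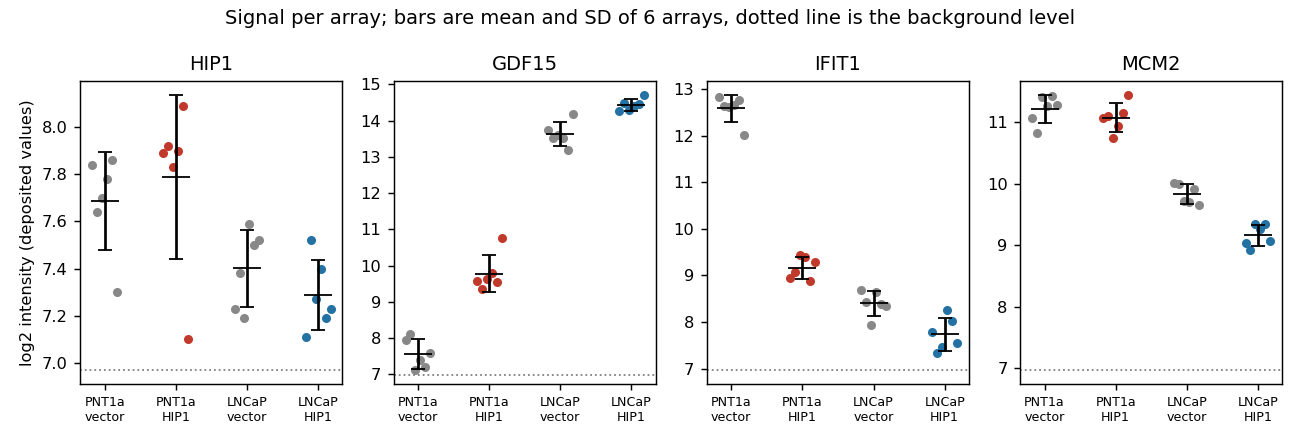
Log2 signal of HIP1, GDF15, IFIT1 and MCM2 on each of the 24 arrays, by cell line and construct, with the mean and SD of each group of 6 and the background level (6.97) as a dotted line. HIP1-labelled and vector arrays overlap for HIP1, GDF15 lies higher in the HIP1-labelled arrays of both lines, IFIT1 lies lower in PNT1a (-3.42), and MCM2 lies lower in LNCaP (-0.67).

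The PNT1a comparison asked which genes differ between HIP1-labelled arrays and arrays of the vector control in a stable line. Interferon-stimulated genes made up most of the largest falls. IFI44L fell by 4.64 on the log2 scale, from 11.66 ± 0.35 to 7.02 ± 0.39 (mean ± SD of 6). Also lower were IFI6 (log2 fold change -4.06), OAS2, an enzyme activated by double-stranded RNA (-3.74), IFIT1 (-3.42), MX2, a restriction factor of viruses (-3.38), and IFIT3 (-3.25). BEX1 (-3.37) and CCND1, which encodes cyclin D1 (-3.17), completed the 8 largest falls, with adjusted p from 6.25e-21 to 2.95e-15.

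The largest fitted rise in PNT1a was that of SPOCK1, a secreted proteoglycan, from 8.23 ± 0.40 to 11.91 ± 0.21 (log2 fold change 3.68, adjusted p = 1.01e-19). The rise of RUNX3, given next as a bound, may be larger. RUNX3, a transcription factor, was below background with vector (6.61 ± 0.05) and at 10.20 ± 0.25 in HIP1-labelled arrays, at least 9.40-fold higher (adjusted p = 1.01e-22). NPY, which encodes neuropeptide Y, was likewise at least 3.26-fold higher and FBLN2, a matrix protein, at least 3.13-fold higher. S100A9, a calcium-binding protein of inflammation, rose by 3.54 and the acute-phase gene SAA4 by 2.27. DDIT4, a stress-induced inhibitor of mTOR signalling, rose by 2.22. GDF15, a stress-responsive cytokine of the TGF-beta superfamily named in advance, rose by 2.22 from 7.56 ± 0.40 to 9.78 ± 0.50 (adjusted p = 9.77e-11). Genes with several probes are ranked here by the most significant one, which for the acute-phase gene SAA1 rose by 2.09, while its other probe rose by 2.94. In each of these 8 rises and 8 falls, all 6 HIP1-labelled arrays lay on one side of all 6 vector arrays.

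All 31 measured interferon-stimulated genes fell in PNT1a, and 31 also passed when adjusted over the list alone. Their median log2 fold change was -1.78 (camera adjusted p = 1.71e-33, and adjusted p = 0.000832 with an estimated correlation). Of 19 cholesterol synthesis genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.56. SCD, a fatty acid desaturase, rose by 1.78 and the sterol sensor INSIG1 by 1.63. HMGCS1, which acts early in the mevalonate pathway, rose by 1.61 and MSMO1 by 1.02. The cholesterol list passed at the preset correlation (camera adjusted p = 1.69e-05) but had adjusted p = 0.247 with an estimated correlation. Of 16 mesenchymal and migration genes, 10 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.33. The largest falls were those of TAGLN (-1.59), the collagen gene COL5A1 (-1.36), ACTA2, smooth muscle actin (-1.28), and THY1 (-1.03). That list had camera adjusted p = 0.00162, and adjusted p = 0.061 with an estimated correlation. Within the 3 residual clusters of PNT1a arrays its median was -0.19, -0.55 and -0.3, and that of the cholesterol list was 0.4, 0.52 and 0.8. With PNT1a fitted alone, the counts were 31 lower interferon-stimulated genes, 14 higher cholesterol genes, and 7 lower and 0 higher mesenchymal genes. Among the lists of other cell types, fibroblast and stromal markers had 1 higher and 3 lower of 5, and leukocyte markers 0 higher and 2 lower of 3. The fibroblast falls were those of ACTA2, THY1 and COL1A1, which are also in the mesenchymal list, so they are not a separate result. The leukocyte falls were those of CD68 and of HBA2, which fell to background. Fibroblast markers (median -0.34) passed fry (adjusted p = 8.67e-07) and the exact permutation of the list mean (adjusted p = 0.0144). Leukocyte markers passed fry (adjusted p = 0.000812) but not the permutation (adjusted p = 0.233). Neither passed camera (adjusted p = 0.202 and 0.276).

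The arrays measure mRNA and not the activity of STAT3 protein. STAT3 mRNA did not differ detectably in PNT1a. Its 3 probes gave log2 fold changes of 0.02 (ILMN_1663618, adjusted p = 0.925), 0.18 (ILMN_2401978, adjusted p = 0.48) and 0.15 (ILMN_2410986, adjusted p = 0.647). Of 21 STAT3 target genes, 7 rose and 3 fell (7 and 3 adjusted over the list alone), and the list did not move in one direction (median 0.16, camera adjusted p = 0.575). CCND1 and MUC1, a membrane mucin that fell by 1.39, went down, and CEBPD, a transcription factor that rose by 1.201, and LRG1, which rose by 1.02, went up. Among 17 JAK-STAT components, 4 rose and 3 fell (4 and 3 adjusted over the list alone; median 0.02, camera adjusted p = 0.941). STAT4, at background with vector, rose by at least 0.70 and IL6, a cytokine that activates STAT3, by 1.09 (adjusted p = 0.032), while the phosphatase PTPN6 (-0.45) and STAT5A (-0.44) fell. The IL6 call was lost on leaving out any 1 of 6 arrays, with adjusted p up to 0.0958. Of 24 genes of clathrin-mediated endocytosis, 2 rose and 7 fell (2 and 7 adjusted over the list alone; median -0.12, camera adjusted p = 0.276). CLTA, a clathrin light chain (-0.65), RAB5C (-0.48), EPS15L1 (-0.45) and AP2M1, a subunit of the AP-2 adaptor (-0.36), fell most. Without HIP1-labelled array 6 the clathrin list had 11 falls, and without HIP1-labelled array 3 it had 4 rises. With PNT1a fitted alone, rises and falls were 6 and 3 for STAT3 targets, 3 and 2 for JAK-STAT components and 1 and 6 for the clathrin list. The clathrin list passed fry (adjusted p = 0.0236) but not the exact permutation of its mean (adjusted p = 0.233).

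Receptor tyrosine kinases and their ligands had 4 rises and 6 falls among 15 genes in PNT1a (4 and 6 adjusted over the list alone; median -0.09, camera adjusted p = 0.276). The EGF receptor ligand HBEGF (-1.94) and the receptors FGFR3 (-1.60), AXL (-0.999) and EPHA2 (-0.61) fell. Of 27 proliferation genes, 1 rose and 8 fell (1 and 8 adjusted over the list alone; median -0.07, camera adjusted p = 0.276). UBE2C, which acts with the anaphase-promoting complex, fell by 1.07 and the spindle motor KIF11 fell by 1.00. AURKA, a mitotic kinase (-0.71), and RRM2, a subunit of ribonucleotide reductase (-0.66), also fell. Without HIP1-labelled array 6 the RRM2 difference was -0.34, and its call was lost on leaving out any 1 of 2 arrays (adjusted p up to 0.0555). Higher and lower counts in the remaining lists were 8 and 4 of 16 for the TGF-beta superfamily, 7 and 4 of 21 for inflammatory cytokines, 4 and 3 of 20 for hypoxia response, 1 and 6 of 17 for p53 response, and 3 and 5 of 24 for the integrated stress and unfolded protein response. They were 3 and 5 of 10 for epithelial adhesion, 4 and 1 of 10 for basal markers, 1 and 2 of 7 for luminal markers, 3 and 1 of 9 for androgen response, and 1 and 2 of 4 for neuroendocrine markers. Camera adjusted p for these 10 lists ran from 0.276 to 0.941. Whether a list moved depends on the test, since fry and the exact permutation of the list mean, which ask whether it moved at all, gave adjusted p = 0.00109 and 0.0289 for receptor tyrosine kinases and 0.00605 and 0.0162 for proliferation. Basal, luminal, neuroendocrine, and fibroblast and stromal markers and androgen response also passed both, with adjusted p up to 0.00102 in fry and 0.0433 in the permutation. The luminal mean was 0.19 but the median 0.03, with 1 called rise and 2 falls, and NPY (at least 1.70) is a member. Epithelial adhesion, the TGF-beta superfamily and leukocyte markers passed fry alone (adjusted p = 0.00742, 0.0191 and 0.000812). With PNT1a fitted alone, rises and falls were 3 and 4 for receptor tyrosine kinases, 1 and 6 for proliferation, 6 and 3 for the TGF-beta superfamily, 5 and 4 for cytokines, 3 and 3 for hypoxia, 1 and 5 for p53 and 3 and 3 for integrated stress. Without HIP1-labelled array 6 there were 9 falls for integrated stress, 5 rises for androgen response and 3 rises each for luminal markers, p53 and proliferation. Cytokines had 7 falls without vector array 6, proliferation 5 falls without vector array 5, integrated stress 5 rises without vector array 1, and hypoxia 2 rises without vector array 6 or HIP1-labelled array 3 or 4. Adjusted over the list alone, the counts differed for epithelial adhesion (4 and 5), luminal markers (3 and 3) and leukocyte markers (1 and 2).

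Across the 12238 probes tested in PNT1a, limma called 4977 (40.7%), of which 2566 were higher and 2411 lower in HIP1-labelled arrays. At least 2-fold changes were seen for 415 of them, 194 higher and 221 lower. All 6 HIP1-labelled arrays lay beyond all 6 vector arrays for 1880 probes (15.4%, where chance gives 0.216%). The called probes with a symbol covered 1989 higher and 1905 lower genes, of which 14 had probes in both directions. Fitting PNT1a alone called 4100 probes, 4072 of them among the 4977, and in simulated data with the real spread of each line 158 of 344 PNT1a calls of the shared fit were false, against 20 of 191 with the line alone. That simulation changed only 200 probes, and the share of false calls depends on how many probes change. It is therefore no estimate of the false share among the 4977. PNT1a arrays numbered 6, vector and HIP1-labelled, stood apart, with mean correlations of 0.942 and 0.919 to their own groups against at least 0.973 for the other PNT1a arrays, and without both the count was 6153, 4725 of them shared, with a median of -1.93 for the interferon-stimulated genes.

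**Figure D2:**
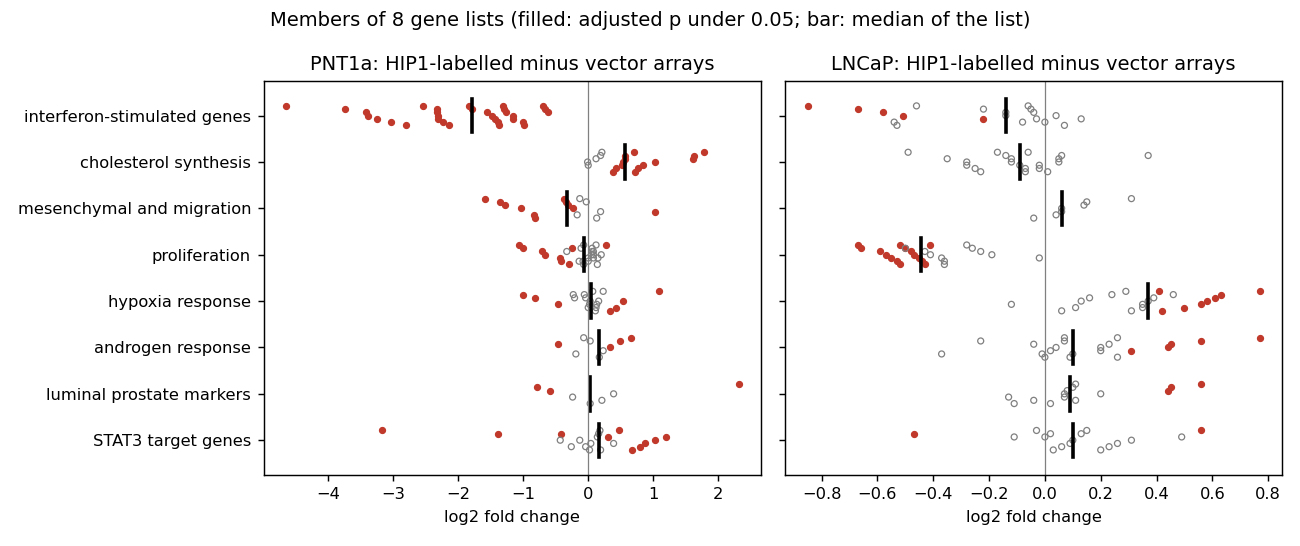
Log2 fold change (HIP1-labelled minus vector arrays) of each measured member of 8 gene lists in PNT1a and in LNCaP, on separate horizontal scales. Filled points have limma adjusted p under 0.05 over all probes, and bars mark the median of each list. Interferon-stimulated genes lie lowest in PNT1a (median -1.78), and proliferation genes lie lowest in LNCaP (median -0.44).

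The LNCaP comparison asked which genes differ between HIP1-labelled and vector arrays of a cancer line 4 days after transfection. Genes of DNA replication and the cell cycle fell in HIP1-labelled LNCaP arrays. ZWINT, a kinetochore protein, fell by 0.73 on the log2 scale, from 9.99 ± 0.18 to 9.26 ± 0.17 (mean ± SD of 6). The replication factors CDC45 (-0.68), MCM2 (-0.67), MCM5 (-0.67), ORC6 (-0.62) and GINS2 (-0.62), the nuclease EXO1 (-0.66) and the thymidine kinase TK1 (-0.66) fell as well, with adjusted p from 8.09e-05 to 0.00418 for these 8 genes, and 6 of 6 HIP1-labelled arrays below all 6 vector arrays. GDF15 had the largest rise among genes whose arrays did not overlap, 0.81, from 13.62 ± 0.33 to 14.43 ± 0.16 (adjusted p = 0.013).

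Next to GDF15, BCHE, which encodes butyrylcholinesterase, rose by 0.65 in LNCaP (adjusted p = 9.17e-05). The olfactory receptor gene OR51E1 rose by 0.62 and the androgen-regulated protease TMPRSS2 by 0.56, from 11.46 ± 0.24 to 12.03 ± 0.17 (adjusted p = 0.00045). NUPR1, a stress-response regulator, rose by 0.61 (adjusted p = 0.0404), MKNK2, a kinase of eIF4E, by 0.56, the histone gene H2BC5 by 0.54 and MAX, the partner of MYC and at background with vector, by at least 0.44. The NUPR1 call was lost on leaving out any 1 of 9 arrays (adjusted p up to 0.112), and that of MKNK2 without vector array 2 (0.50, adjusted p = 0.0534). The GDF15 difference stayed at 0.81 with no filter on dim probes, where its adjusted p was 0.051, and its adjusted p over the alternatives reached 0.0979.

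Of 26 proliferation genes measured in LNCaP, 15 fell and 0 rose (23 and 0 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 8.06e-30, and adjusted p = 1.35e-05 with an estimated correlation). With LNCaP fitted alone 22 fell, and without the 3 arrays of the smaller residual cluster (vector 3 and 4, HIP1-labelled 4) 10 fell, with a median of -0.47 over the 9 arrays left. Beside MCM2 and MCM5, cyclin A2 (CCNA2, -0.59) and the mitotic kinase AURKB (-0.57) fell. Of 21 hypoxia response genes, 8 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 1.61e-13, and adjusted p = 0.0164 with an estimated correlation). NDRG1 rose by 0.77, the collagen hydroxylase P4HA1 by 0.63, PFKFB4, a regulator of glycolysis, by 0.61 and ERO1A, an oxidase of the endoplasmic reticulum, by 0.58. The hypoxia count was 14 with LNCaP fitted alone and 4 without the smaller residual cluster, where the median was 0.37 as over all arrays (exact permutation of the list mean, adjusted p = 0.0241). LNCaP vector array 6 had a mean over the list (10.41) within the range of the HIP1-labelled arrays (10.24 to 10.57), while the other vector arrays lay at 9.76 to 10.07. Androgen response genes had 5 rises and 0 falls among 21 (8 and 1 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 1.61e-05, and adjusted p = 0.00554 with an estimated correlation). The androgen count was 8 rises and 1 fall with LNCaP fitted alone and 2 rises without the smaller residual cluster, where the median was 0.10. NDRG1 and TMPRSS2 were among them, with the kallikrein KLK2 (0.45) and FOLH1, which encodes prostate-specific membrane antigen (0.44). Luminal prostate markers had 3 rises of 14, namely TMPRSS2, KLK2 and FOLH1 (3 and 0 adjusted over the list alone; median 0.09, camera adjusted p = 0.00168, and adjusted p = 0.0131 with an estimated correlation). Of only 2 basal markers measured, EGFR rose by 0.59 (1 adjusted over the list alone; camera adjusted p = 0.0107, and adjusted p = 0.0476 with an estimated correlation).

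Interferon-stimulated genes had 5 falls and 0 rises of 20 in LNCaP (8 and 0 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 4.08e-05, but adjusted p = 0.188 with an estimated correlation). With LNCaP fitted alone 8 fell, and without the smaller residual cluster 2 fell, with a median of -0.15. The count was 1 without HIP1-labelled array 6, 2 without vector array 1 or 4 or HIP1-labelled array 2, and 3 without vector array 2 or 5 or HIP1-labelled array 1 or 3. The falls were -0.67 for IFIT1 (adjusted p = 0.0101), -0.85 for ISG15, a ubiquitin-like modifier (adjusted p = 0.0226), -0.58 for IFITM1 (adjusted p = 0.0215), -0.51 for IFIT2 (adjusted p = 0.0495) and -0.22 for OAS3 (adjusted p = 0.0261), named after its values were seen. The call of ISG15 was lost on leaving out any 1 of 6 arrays, that of IFITM1 on leaving out any 1 of 4, and that of IFIT2 on leaving out any 1 of 18, with adjusted p up to 0.075, 0.0675 and 0.144. The OAS3 call was lost on leaving out LNCaP vector array 2 (-0.18, adjusted p = 0.0881) or HIP1-labelled array 2, 5 or 6 (adjusted p = 0.0851, 0.055 and 0.0583). Cholesterol synthesis genes had 0 called members of 21 (0 higher and 2 lower adjusted over the list alone; median -0.09, camera adjusted p = 0.0107, but adjusted p = 0.355 with an estimated correlation), with values of -0.49 for ACAT2 and 0.37 for SCD. Epithelial adhesion genes had 0 called of 15 (4 higher adjusted over the list alone; camera adjusted p = 0.0107, but adjusted p = 0.154 with an estimated correlation), with values of 0.27 for DSP and 0.24 for CLDN3. The integrated stress and unfolded protein response had 0 called of 27 (0 adjusted over the list alone; camera adjusted p = 0.00967, but adjusted p = 0.443 with an estimated correlation), with values of 0.42 for DNAJB9 and 0.36 for CEBPG. With LNCaP fitted alone limma called 8 integrated stress genes higher and 0 lower, 3 epithelial adhesion genes higher and 0 lower, and 1 cholesterol gene higher and 5 lower. Without both PNT1a arrays numbered 6 the counts were 3 higher, 3 higher and 4 lower. Integrated stress had 1 rise without PNT1a vector array 6 and 2 without PNT1a HIP1-labelled array 6, and the exact permutation of its list mean (0.135) had adjusted p = 0.0216. Cholesterol had 2 falls on leaving out the one or the other of these arrays and 1 without PNT1a HIP1-labelled array 4 or LNCaP vector array 6. Epithelial adhesion had 1 rise without PNT1a HIP1-labelled array 6 or LNCaP vector array 6. Without LNCaP vector array 3 epithelial adhesion had camera adjusted p = 0.0742. The exact permutation of the list mean had adjusted p = 0.0253 for interferon-stimulated genes and 0.0108 for cholesterol synthesis, where fry gave adjusted p = 0.0623 and 0.22.

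STAT3 mRNA did not differ detectably in LNCaP, with log2 fold changes of 0.07, 0.13 and 0.14 for its 3 probes (adjusted p = 0.926, 0.86 and 0.893). Of 17 STAT3 target genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone; median 0.10, camera adjusted p = 0.266). With LNCaP fitted alone 4 rose and 1 fell, and the exact permutation of the list mean (0.12) had adjusted p = 0.0371, so whether STAT3 targets moved in LNCaP depends on the test. Over all arrays, 0 rose without vector array 2, 3, 4 or 5 or HIP1-labelled array 2, 5 or 6. VEGFA rose by 0.56 (adjusted p = 0.0288, lost on leaving out any 1 of 7 arrays, with adjusted p up to 0.0979), and BIRC5, which encodes survivin, fell by 0.47. RAB7A, a GTPase of late endosomes, was the single called gene of clathrin-mediated endocytosis among 23 (0.30, adjusted p = 0.0241, lost on leaving out any 1 of 5 arrays, with adjusted p up to 0.0791; median 0, camera adjusted p = 0.957). Called genes in the other lists, all higher, were 1 of 12 JAK-STAT components and 1 of 9 receptor tyrosine kinases and ligands (EGFR in both), 1 of 12 in the TGF-beta superfamily and 1 of 17 in p53 response (GDF15 in both), and 1 of 5 neuroendocrine markers (ENO2, 0.73, adjusted p = 0.0182, and 0.0685 at most on leaving out 1 array). Mesenchymal genes (7 measured), inflammatory cytokines (8), fibroblast markers (3) and leukocyte markers (1) had 0 called by limma over all probes. With LNCaP fitted alone the TGF-beta superfamily had 1 rise and 3 falls, p53 response 3 rises and 1 fall, neuroendocrine markers 1 and 1, mesenchymal genes 1 rise and cytokines 1 fall. The exact permutation of the list mean passed receptor tyrosine kinases (adjusted p = 0.0108), p53 response (0.0144), neuroendocrine markers and cytokines (0.0253 for both) and the TGF-beta superfamily (0.03), none of which passed camera or fry.

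Across the 12022 probes tested in LNCaP, limma called 343 (2.9%), of which 128 were higher and 215 lower, covering 109 higher and 187 lower genes. Differences ran from -0.85 to 0.87, so 0 called probes reached 2-fold in limma, while 1719 had an unadjusted p under 0.05. For 485 probes (4%, where chance gives 0.216%) the arrays of both groups did not overlap. The count was 1065 when LNCaP was fitted alone, which included 340 of the 343, and 1013 without both PNT1a arrays numbered 6. Leaving out LNCaP HIP1-labelled array 2 or 6, or vector array 2 or 5, brought it to 189, 208, 219 and 200, and leaving out PNT1a HIP1-labelled array 6 to 558. PNT1a arrays act on LNCaP calls only through the shared spread and do not move an LNCaP fold change.

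The difference between HIP1-labelled and vector arrays, called the effect here, was then compared between the lines, which also differ in stable against transient transfection. Interferon-stimulated genes differed most as a list: 30 of 32 had a higher effect in LNCaP than in PNT1a (31 adjusted over the list alone), with a median of 1.59 for the LNCaP effect minus the PNT1a effect (camera adjusted p = 7.42e-36, and adjusted p = 0.000778 with an estimated correlation). Many of these genes are at background in LNCaP, so the lists were also restricted, after the result was seen, to genes tested in both lines. Of 19 such interferon-stimulated genes 18 had a higher effect in LNCaP, with a median of 1.69 (camera adjusted p = 1.3e-22, and adjusted p = 0.00377 with an estimated correlation). Besides the genes already named, HERC6 (2.84) and HELZ2 (2.75), both interferon-inducible, and RHOBTB3 (2.61) fell in PNT1a (-2.80, -2.496 and -2.44 in that order), with LNCaP values of 0.04, 0.25 and 0.17. NDN fell to background in PNT1a, with a bound of -2.10, and had 0.004 in LNCaP. ARHGDIB (-2.58 in PNT1a) and SAA1 (2.94 in PNT1a) were at background in LNCaP, so the difference between lines is not measured for them. Cholesterol synthesis genes had a median difference of -0.66 (15 of 21 called, all lower; 18 adjusted over the list alone; camera adjusted p = 2.12e-07, but adjusted p = 0.0993 with an estimated correlation). Mesenchymal genes had 7 of 16 called, all higher (7 higher and 1 lower adjusted over the list alone), and a median of 0.34 (camera adjusted p = 0.000336, and adjusted p = 0.0293 with an estimated correlation), but only 7 were tested in both lines, of which 3 were called higher (median 0.37, camera adjusted p = 0.00579, and adjusted p = 0.0309 with an estimated correlation). Proliferation genes had 2 higher and 13 lower of 27 (2 and 15 adjusted over the list alone) and a median of -0.34 (camera adjusted p = 0.00515, but adjusted p = 0.33 with an estimated correlation). Hypoxia genes had 9 higher and 1 lower of 22 (9 and 1 adjusted over the list alone) and a median of 0.23 (camera adjusted p = 0.0058, but adjusted p = 0.43 with an estimated correlation). The GDF15 rise was larger in PNT1a than in LNCaP (-1.41, adjusted p = 0.000175). In LNCaP GDF15 lay above the 99th percentile of the deposited values (12.33), and whether signal near the top of the range limits a rise was not tested. In all, limma called 3480 of 13946 probes for the difference, 1684 higher and 1796 lower in LNCaP relative to PNT1a, and 2650 of the 10314 probes tested in both lines. Most of this count comes from the PNT1a effect, since splitting only the LNCaP labels gave 2921 to 3497. Among the latter the cholesterol, proliferation and hypoxia lists had medians of -0.79, -0.34 and 0.22 (19, 26 and 19 genes).

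GDF15, NUPR1, ISG15, IFIT1, IFITM1 and PIMREG changed in the same direction in both lines. GDF15 and NUPR1 (1.12 in PNT1a) rose, and ISG15 (-2.54 in PNT1a), IFIT1, IFITM1 (-1.37 in PNT1a) and PIMREG (-0.95 in PNT1a and -0.54 in LNCaP) fell. In opposite directions, RNASEH2A (0.48 and -0.60) and E2F2 (0.47 and -0.58) rose in PNT1a and fell in LNCaP, and ADM (-1.004 and 0.50), HSPA6, CXCR4 and RPS29 (-0.48 and 0.46) fell in PNT1a and rose in LNCaP. HSPA6 and CXCR4 had groups at background, which gives bounds of -0.36 in PNT1a for HSPA6 (0.51 in LNCaP) and of -0.43 and 0.38 for CXCR4. The LNCaP calls of ADM, HSPA6, CXCR4 and RPS29 were lost on leaving out any 1 of 2, 6, 9 and 8 arrays (adjusted p up to 0.078, 0.0715, 0.0952 and 0.122), and the PNT1a call of CXCR4 on leaving out any 1 of 3 (adjusted p up to 0.0676). Of 10314 probes tested in both lines, 36 were higher in both where independent lists would share 16.6 (one-sided Fisher's exact p = 9.97e-07, adjusted p = 3.99e-06). For probes lower in both the count was 48 against 37.8 (p = 0.0407, adjusted p = 0.0814, Fisher's exact test). The other direction pairs held 47 against 39.4 (Fisher's exact p = 0.101, adjusted p = 0.135) and 15 against 15.9 (Fisher's exact p = 0.645). In total 84 probes were called in the same direction and 62 in opposite directions. Across probes the log2 fold changes of the lines correlated weakly, with Pearson r of 0.112 and Spearman rho of 0.093. Fisher's test takes probes as independent, which they are not, and 11 of 100 splits of the arrays gave an r as high as 0.112. The count of 84 fell to 44, 45, 45 and 47 without LNCaP HIP1-labelled array 2 or 6 or vector array 5 or 2, and was 167 without PNT1a HIP1-labelled array 6.

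Markers of line identity separated the vector arrays. KLK3, which encodes prostate-specific antigen, was at background in PNT1a (6.26 ± 0.13, mean ± SD of 6) and at 7.93 ± 0.26 in LNCaP, at least 1.94-fold higher (adjusted p = 1.03e-15). VIM, which encodes vimentin, was 12.71 ± 0.17 in PNT1a and 7.63 ± 0.17 in LNCaP (difference -5.08, adjusted p = 7.97e-27, and -4.79 by a second probe). CAV1, caveolin-1, was at background in LNCaP by both probes, at least 13.4-fold and 1.88-fold lower than in PNT1a. The basal keratin KRT5 was at background in both lines, at 6.31 ± 0.05 and 6.42 ± 0.08. No chip is given in the sources used here, so line and chip are not told apart.

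**Figure D3:**
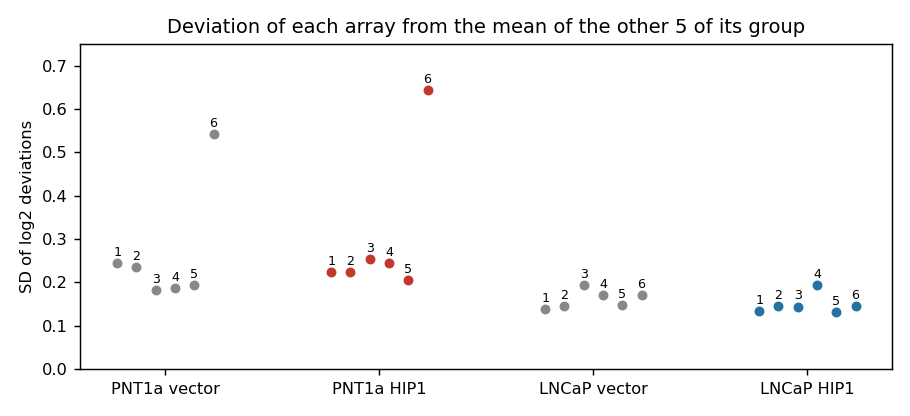
SD over expressed probes of the log2 deviation of each array from the mean of the other 5 arrays of its group, for the 4 groups of 6 arrays, with replicate numbers beside the points. PNT1a arrays numbered 6 lie at 0.54 (vector) and 0.64 (HIP1-labelled), and the other PNT1a arrays lie between 0.18 and 0.25.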

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

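The tests of the PNT1a arrays numbered 6 for random noise and for a shared handling factor, and the tests weighing why HIP1 signal was not higher and why interferon-stimulated genes were lower, were chosen after the result was seen, as was splitting a single line for the difference, while the other splits of the samples and the test for LNCaP RNA were chosen before.

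PNT1a vector array 6 and HIP1-labelled array 6 stood apart from the other 5 arrays of their groups. The SD of their deviation from the rest of their group was 0.54 and 0.64, with a gap to the next array of 0.826 and 0.886 of the range in their group, above Dixon's 95% critical value for 6 arrays. Of 216 groups tested for an outlying array, 34 had one, against 10.8 expected by chance, and 20 of the 34 were these arrays. In HIP1-labelled array 6 the gap was 0.693 for GDF15 (high), 0.676 for OAS2 (high), 0.773 for NUPR1 (high), 0.743 for HIP1 (low), 0.689 for RRM2 (low), 0.66 for INSIG1 (low) and 0.642 for MSMO1 (low). In vector array 6 it was 0.645 for CLTA and 0.733 for E2F2 (both high). It was 0.635 for IFI6, 0.728 for IFIT1, 0.734 for BEX1, 0.881 for STAT3 (ILMN_2410986), 0.669 for MUC1, 0.844 for CEBPD, 0.637 for LRG1, 0.687 for CXCR4 and 0.75 for RPS29 (all low).

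The deviations of the arrays numbered 6 correlated with each other at r of 0.70 across expressed probes, with EGR1 (2.73), SLC25A51 (2.13) and ASNS (2.07) high and ACTG1 (-2.98), C1R (-2.79), UBE2L6 (-2.45) and ALDOA (-2.29) low on average, genes chosen after their values were seen. Random noise that is independent on each array is argued against by that r of 0.70. The spread on background probes was 1.05 times that of the other 10 arrays, while the spread on expressed probes was 2.71 times. This contrast cannot decide on noise. The background probes were chosen to lie below the background level on these arrays too, and all arrays share a single distribution, which limits their spread. LNCaP RNA in these samples is argued against, since 100 probes bright in LNCaP deviated by a median of 0.008 where a 10% share would raise them by 0.97. A handling or RNA quality factor shared with other arrays stays open and is a candidate explanation: the highest correlation with an LNCaP array was 0.33, and the highest of any other PNT1a array was 0.29, a narrow margin. No biological explanation was tested, since the labels give none.

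The HIP1 signal was not detectably higher in HIP1-labelled arrays of either line. A signal lost in background is argued against, since all 24 arrays lay above the background level for HIP1. A probe outside the cloned part of HIP1 could explain it and cannot be told apart from a construct that is weakly expressed, since the probe position is not given in the sources used here. The upper end of the interval in PNT1a allows a 1.27-fold rise of what the probe measures.

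The interferon-stimulated genes were lower in HIP1-labelled PNT1a arrays, by a median of -1.78 over 31 genes. The arrays numbered 6 are argued against as the source, since the median was -1.93 without them (-1.934). Clusters of residuals that cross the groups were not tested by using them as a block (-1.777), since each cluster holds as many vector as HIP1-labelled arrays and the block cannot move a fold change. Within the 3 clusters the medians were -1.82, -1.97 and -1.26. A difference between the stable lines that does not come from HIP1, such as selection of a subpopulation or a response to the vector, could also give this pattern. In LNCaP the median was -0.14 after transient transfection, and this explanation cannot be told apart from an effect of the construct, since the design has a single stable pair of lines and LNCaP was transfected in another way.

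The remaining outlying arrays are given with the gap as a share of the range of the group. In PNT1a they were FBLN2 in HIP1-labelled array 3 (0.637, low) and STAT3 in HIP1-labelled array 1 (0.777 for ILMN_1663618 and 0.631 for ILMN_2401978, low). In LNCaP they were STAT3 in HIP1-labelled array 4 (0.641, 0.655 and 0.704 for its 3 probes, low), OR51E1 in HIP1-labelled array 5 (0.747, low), CDC45 in HIP1-labelled array 2 (0.652, low), ERO1A in HIP1-labelled array 6 (0.633, high) and AURKB in vector array 3 (0.698, low). LNCaP vector array 6 was high for DSP (0.759), EGFR (0.7) and CXCR4 (0.696), and its mean over the hypoxia list (10.41) lay among the HIP1-labelled arrays (10.24 to 10.57), above the other vector arrays (9.76 to 10.07), and LNCaP HIP1-labelled array 4 had the widest deviation of its group (0.778).

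The effect (HIP1-labelled minus vector arrays) differed between the lines for 3480 probes and for 78 of the genes named in the report, given here as the LNCaP effect minus the PNT1a effect (log2, limma adjusted p under 0.05). These are fitted values. RUNX3, S100A9, NPY, SAA4, SAA1, FBLN2, LRG1, STAT4, IFI44L, OAS2, MX2, MUC1, STAT5A, AXL, EPHA2, COL5A1, THY1 and ARHGDIB were at background in both LNCaP groups, so for them the value restates the PNT1a effect and is no measured difference. The same holds the other way round for BCHE, OR51E1, TMPRSS2, MAX, KLK2 and FOLH1, which were at background in both PNT1a groups, and STAT4, RUNX3, NPY, FBLN2, IFIT3, MAX, DSP, NDN, HSPA6 and CXCR4 had a single group of a line at background. Among genes higher in PNT1a, it was -3.57 for SPOCK1, -3.58 for RUNX3, -3.62 for S100A9, -2.27 for NPY, -2.33 for SAA4, -2.85 for SAA1, -1.41 for GDF15, -2.43 for DDIT4, -2.16 for FBLN2, -1.20 for CEBPD, -0.99 for LRG1 and -0.80 for STAT4. For cholesterol synthesis genes it was -1.42 for SCD, -1.62 for INSIG1, -1.63 for HMGCS1 and -1.14 for MSMO1. Among interferon-stimulated genes it was 4.50 for IFI44L, 3.59 for IFI6, 3.47 for OAS2, 2.75 for IFIT1, 3.34 for MX2, 2.94 for IFIT3, 1.69 for ISG15, 0.79 for IFITM1, 1.80 for IFIT2, 2.84 for HERC6 and 2.75 for HELZ2. In LNCaP vector arrays IFI6 and IFIT1 lay too close to background to fall as far as in PNT1a. Other genes lower in PNT1a gave 3.21 for BEX1, 3.26 for CCND1, 1.36 for MUC1, 0.46 for PTPN6, 0.52 for STAT5A, 0.60 for CLTA, 0.42 for RAB5C, 0.40 for EPS15L1, 2.00 for HBEGF, 1.53 for FGFR3, 1.02 for AXL, 0.65 for EPHA2, 0.55 for UBE2C and 0.72 for KIF11. They also gave 1.74 for TAGLN, 1.37 for COL5A1, 1.42 for ACTA2, 1.09 for THY1, 2.77 for NDN, 2.66 for ARHGDIB and 2.61 for RHOBTB3.

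Among genes named for LNCaP, the difference was 0.65 for BCHE, 0.68 for OR51E1, 0.43 for TMPRSS2, 0.68 for H2BC5, 0.56 for MAX, 0.60 for VEGFA, 0.46 for RAB7A, 1.22 for NDRG1, 0.42 for KLK2, 0.56 for FOLH1, 0.49 for PFKFB4 and 0.56 for ERO1A. For cell cycle genes it was -0.88 for ZWINT, -0.96 for CDC45, -0.54 for MCM2, -0.73 for MCM5, -0.72 for EXO1, -0.55 for TK1, -0.83 for GINS2, -0.51 for BIRC5 and -0.50 for AURKB. It was 1.11 for DSP, -0.77 for DNAJB9 and 0.66 for CEBPG. For genes called in opposite directions it was 1.03 for HSPA6, 1.51 for ADM, -1.08 for RNASEH2A, -1.05 for E2F2, 1.09 for CXCR4 and 0.93 for RPS29. Of the 3480 probes, 2627 were tested in both lines. Gene lists differed by medians of 1.59 (interferon-stimulated genes), -0.66 (cholesterol synthesis), 0.34 (mesenchymal genes), -0.34 (proliferation) and 0.23 (hypoxia response). The difference was not called for HIP1 (-0.21, adjusted p = 0.407) or NUPR1 (-0.52, adjusted p = 0.108).

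The part that chance could play was tested with 100 splits of the 12 arrays of each line. For the PNT1a count a chance division of the arrays is argued against: 1 of the 100 splits, the real one, called as many as 4977 probes, and the highest other called 4449. That other split had 5 arrays of one label together, and the median of the other splits was 0. The splits take the arrays of a line as independent. They do not sample differences between cultures or between stable lines, of which PNT1a has a single pair, so chance of that kind is not excluded. A chance division of the arrays is argued against for the LNCaP count as well (1 of 100 splits, 343 probes against 24 in the highest other). The same holds for the difference between lines (1 of 100 splits of both lines, 3480 probes against 1321). Most of that count comes from the PNT1a effect: with the PNT1a labels kept and only the LNCaP arrays split, it ran from 2921 to 3497, and 2 of 99 other splits reached 3480, while with only the PNT1a arrays split it reached 1897 at most. Chance is not excluded for the number of lists passing camera: 39 of 100 splits gave as many as the 3 in PNT1a, up to 10 in another split, and 6 of 100 splits gave as many as the 9 in LNCaP, up to 10. Nor is it excluded for the correlation between the lines, where 11 of 100 splits reached the r of 0.112 and the highest other was 0.2.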

How the results depend on the processing

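Chosen after the result was seen were normexp on the linear scale, cyclic loess, leaving out the PNT1a arrays numbered 6 or the smaller LNCaP residual cluster, the residual cluster block, the restriction to probes tested in both lines and the exact permutation of list means.

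Of 1670 comparisons of 156 named-gene results with an alternative, 1554 kept direction and call, 66 kept direction and lost the call, 39 gained it and 11 reversed. The losses were most frequent with no filter (20), normexp (17) and without the smaller LNCaP cluster (15). With 1 array left out, 3608 of 3744 kept both, 122 lost the call, 6 gained it and 8 reversed.

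The LNCaP count of 343 was 154 with no filter, where more probes are tested, 1065 with each line alone, 1374 with array weights, 0 at 2-fold (limma, 1719 at unadjusted p under 0.05), 93 with normexp, 1013 without PNT1a arrays numbered 6 (1065 if also fitted alone), 976 with the residual cluster block and 139 without the smaller LNCaP cluster, where fewer arrays remain. With 1 array left out it ran from 189 (LNCaP HIP1-labelled 2) to 558 (PNT1a HIP1-labelled 6), with 200 and 219 without vector 5 and 2 and 208 without HIP1-labelled 6. The PNT1a count of 4977 became 415 at 2-fold, and the difference count of 3480 became 424 at 2-fold and 5415 with weights, and 2650 among probes tested in both lines. The 84 probes called in the same direction were 31 with no filter, 211 with each line alone, 416 with weights, 0 at 2-fold, 21 with normexp, 305 without arrays numbered 6 (309 also alone), 323 with the cluster block and 33 without the smaller LNCaP cluster. With 1 array left out they ran from 44 to 167, at the same arrays. Leaving out PNT1a arrays cannot move an LNCaP fold change, since each group has its own mean, and acts on LNCaP calls only through the shared spread. For normexp, weights and the cluster block the cause was not tested, and in PNT1a the block is balanced over the groups and cannot move a fold change.

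GDF15 in LNCaP kept its direction and lost its call with no filter (0.812, adjusted p = 0.051), with normexp (0.814, adjusted p = 0.0726) and without the smaller LNCaP cluster (0.791, adjusted p = 0.0979). The HIP1 level in PNT1a ran from 0.02 to 0.236 with 1 array left out and was called only without HIP1-labelled array 6 (adjusted p = 0.0312, others 0.0611 to 0.908).

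With an estimated correlation 1 list passed in PNT1a and 5 in LNCaP, against 3 and 9 at the preset. Fry passed 14 and 6, and the exact permutation of list means 10 and 14, where 0.00216 is the smallest p it can give. Fry and the permutation ask whether a list moved at all, camera whether it moved more than other genes. The mesenchymal list in PNT1a had camera adjusted p = 0.0549 with no filter. Epithelial adhesion in LNCaP lost its call with normexp (0.056), the cluster block (0.0919), without the smaller cluster (0.142) and in the exact permutation (0.0595).

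The reversals were all of uncalled values, and the cause was not tested. STAT3 in PNT1a by ILMN_1663618 was -0.142 with weights and -0.128 without arrays numbered 6 (also alone), and ran from -0.123 to 0.121 with 1 array left out. By ILMN_2401978 it was -0.039 and -0.012, and by ILMN_2410986 it ran from -0.064 to 0.339 with 1 array left out. STAT3 in LNCaP by ILMN_1663618 was -0.017 with the cluster block and -0.002 without the smaller cluster, and ran from -0.037 to 0.165. By ILMN_2401978 it was -0.018 without the smaller cluster, and by ILMN_2410986 -0.001 with the block and -0.019 without the cluster. The JAK-STAT list in PNT1a was 0.019 with the stricter filter (direction of camera turned), -0.09 with weights and -0.074 without arrays numbered 6 (also alone), from -0.075 to 0.061 with 1 array left out. The clathrin list in LNCaP was -0.019 with no filter and -0.017 with the block, from -0.027 to 0.018 with 1 array left out. PDGFRA in LNCaP, an uncalled value, ran from -0.05 to 0.079.

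With the replicate number as a block the LNCaP count was 645 and the shared count 198. The numbers do not pair the samples: residuals of vector and HIP1-labelled arrays with the same number correlated at r of -0.04, 0.06, 0.01, -0.01, 0.33 and 0.70 in PNT1a and 0.09, -0.04, -0.24, 0.32, 0.05 and 0.13 in LNCaP.

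Not run were plain log2 of the raw table with quantile normalization, normexp with median scaling and normexp with cyclic loess from the raw table, whose identifiers are not paired with probe names, and a chip block, since no chip is given. The deposited table is itself the source of the values above, and each line alone gives no value for the difference. Normexp and cyclic loess moved the median of all effects by at most 0.003. Signal over background limits what was tested: 31223 of 48803 probes lay below the background level on all arrays.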

Other observations

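The gene families and the comparison of replication with mitosis genes given here were all chosen after the result was seen.

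TRIM genes, many of them inducible by interferon, fell in HIP1-labelled PNT1a arrays: 16 of 29 were lower and 2 higher, with a median of -0.20 (camera adjusted p = 0.027, adjusted p = 0.0332 with an estimated correlation, and 0.0503 without the arrays numbered 6). TRIM22 (-1.24), TRIM8 (-0.87), TRIM25 (-0.83), TRIM5 (-0.69) and TRIM21 (-0.61) fell, and TRIM6 rose by 0.68. The median was -0.20 with cyclic loess and -0.27 with normexp, and in LNCaP it was 0.01. Among 16 collagen genes in PNT1a, 7 were higher and 6 lower, with COL12A1 at 1.17 and COL5A1 at -1.36. The hair keratin KRT34 fell to background, with a bound of -1.68 (adjusted p = 4.17e-16). Of 70 ribosomal protein genes, 11 were higher and 10 lower in PNT1a, and their median of 0.03 was 0 with cyclic loess.

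Tubulin genes were lower in HIP1-labelled LNCaP arrays, with a median of -0.23 over 17 genes (-0.24 with cyclic loess and -0.28 with normexp), of which 3 were called (camera adjusted p = 7.12e-05, adjusted p = 0.0557 with an estimated correlation). They were TUBG1 (-0.49), TUBA1B (-0.36) and TUBA1A (-0.34). Proteasome genes had a median of -0.08 with 0 of 36 called by limma (camera adjusted p = 0.016, adjusted p = 0.457 with an estimated correlation), and mitochondrial ribosomal protein genes -0.06 with 0 of 76 called (camera adjusted p = 0.0435, adjusted p = 0.676 with an estimated correlation).

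Replication genes may have fallen more than mitosis genes in LNCaP, a hypothesis formed from the falls of CDC45, MCM2 and GINS2. Of 25 replication genes 21 were called lower (median -0.46), and of 29 mitosis genes 15 were (median -0.41). The difference of the list means was -0.098 (exact permutation p = 0.00433 over 924 splits). The small p does not count for the hypothesis, since the lists were chosen after these falls were seen in the same arrays. A difference within 0.1 was set to count against it, and -0.098 lies within that bound by a narrow margin. A lower difference with an exact permutation p under 0.05 was set to count for it, and that was met too. With both rules met, the test cannot decide on the hypothesis.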
